A study of Mus musculus with 12 samples.

How the data were processed

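The series holds 12 arrays of 4 mouse iPS lines, 3 cultures per line, hybridised with biotin-labelled cDNA from total RNA after whole-transcript amplification, per the labels' protocols. The deposited values are probe set intensities on a linear scale, with 1 value per probe set and array. The submitters' processing notes name GCOS 1.4; the method of summarising probes into probe sets, the background correction and the normalization are not given in the sources used here. The values were already brought to a common level across arrays. The lower quartile, the median and the upper quartile of log2 values differed over the 12 arrays by at most 0.0574, 0.0833 and 0.0954, each below the limit of 0.1 set for using the values as deposited, so the scale was not changed further. The lowest value per array lay between 3.06 and 3.70 and the highest between 14642 and 16531. Because the table was linear, each value was turned into log2(value + 1), which understates the change of dim genes.

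Of 35556 probe sets, 6617 have identifiers below the lowest identifier in the array annotation, which lists no gene for any of them. They were treated as the block of control probe sets and left out of the tests, a choice made after the table and its counts over all probe sets had been seen; the identification as controls rests on the numbering alone. Of the 28939 tested probe sets, 21789 list 1 gene, 1621 several and 5529 none. A gene with several probe sets is represented by the one with the highest mean over the 12 arrays, which gives 19939 genes. Current symbols were taken by gene identifier from a RefSeq gene table of the assembly GRCm38.p6, which matched 19856 of them; the other 83 keep the symbol of the array annotation. Probe sets that list several genes name no gene. Chromosome numbers and gene order come from that table. The annotation of the array names no genome build, so no coordinates are given. Among the genes always reported, Mirg and Ddx3y had no probe set of their own and are not analysed here.

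Arrays were grouped by line, and lines by competence, as the labels give them. No pair of arrays shared more than 0.746% of identical values, so no array was counted as a repeat of another. The p-values between lines measure the spread between cultures of a line, whereas competence is a property of a line.

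Tests were run with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over the 28939 probe sets, threshold 0.05). The pairs of lines come from a fit of 4 line means over all 12 arrays, which share an estimate of the spread with 8 residual degrees of freedom and 4.06 from the prior. Competence was tested with the line as a random block (duplicateCorrelation, consensus correlation 0.183). A further count gives the probe sets past the threshold in the same direction in all 4 pairs of a competent and another line, and the other 2 ways of dividing the lines into pairs were fitted in the same manner. The 26 gene lists were tested with camera, with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. For competence, the test with an estimated correlation had no term for the line. The number of members past the threshold is given over all probe sets and adjusted over the list alone.

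Before the value files were opened, the comparisons, the gene lists, the alternatives and the rule for named genes were fixed. For competence the rule takes up to 10 genes in each direction that passed in all 4 pairs. Within a competence class it takes the 5 genes with the largest log2 difference in each direction among those called. It also takes 16 genes of pluripotency, the Dlk1-Dio3 domain and the sex chromosomes in every comparison, and up to 4 members with the smallest p from each list in the comparison under which the list is described. The text names part of the genes this rule allows, and that part was chosen after their values were seen. Zfp943, Dusp9, Dnmt1, Dnmt3l, Baiap2l1, Vim, Fn1, Thbs1, Acta2 and the gene families fall outside the rule, were chosen after seeing values and were not followed through the alternatives.

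The tests were tried on simulated data with the probe sets and spreads of these arrays. For LiPS-47 against LiPS-50, 73.1% of changes of 1.5-fold, 94.0% of 2-fold and 100% of 4-fold were recovered, and 9 of 187 calls were false. For the competence test 91.0%, 100% and 100% were recovered, but 32 of 226 calls were false, so its threshold was more lenient than stated. The simulated lines differed from each other by a small random amount only, and none stood apart as LiPS-50 did. These shares therefore do not give the power of the competence test on the real arrays. In the simulation of gene lists for LiPS-47 against LiPS-50, the 1 shifted set of 21 was called and 0 others.

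Alternatives were the replicate number as a block, median centring of each array, quantile normalization, removal of probe sets with a mean below the 40th percentile, an intensity trend with a robust prior, values averaged per gene, a pseudocount of 16, at least a 2-fold difference, each culture left out, and a fit of 2 lines alone. For competence they also were line means, no term for the line, a contrast of fixed line means and each line left out. Chosen after seeing the data were the tests that include the control block and the gene lists without X- and Y-linked members.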

Results

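Gene expression was measured in 4 lines of mouse induced pluripotent stem (iPS) cells, which are cells returned to an embryonic stem cell-like state, here from embryonic fibroblasts of the C57BL/6J strain with 3 factors. Per the labels, LiPS-45 and LiPS-57 had tetraploid complementation competence and LiPS-47 and LiPS-50 did not. In tetraploid complementation, stem cells are placed in an embryo made tetraploid, whose own cells mainly form the extraembryonic tissues, so that the fetus itself derives from the stem cells. Each line was represented by 3 cultures, described as biological repeats, with 1 Affymetrix array each, which makes 12 arrays. The series asked how expression differs between iPS cells with and without this competence. The number of arrays and of lines limits the precision, because the competence question rests on 2 lines against 2 lines. Between arrays of the same line the mean correlation of log2 values lay between 0.996 and 0.997. All values below are on the scale log2(intensity + 1) unless a fold is given, and spreads are standard deviations (SD) over 3 cultures.

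In the competence test with the line as a random block, no gene separated the competent from the other lines at an adjusted p of 0.05. Pou5f1 (Oct4), the central transcription factor of pluripotency, was measured at 11.74 ± 0.0417 in LiPS-45, 11.72 ± 0.00665 in LiPS-57, 11.69 ± 0.0382 in LiPS-47 and 11.56 ± 0.0322 in LiPS-50 (SD, n = 3 each). Its difference between competent and other lines was 0.11 (standard error, SE, 0.0538), with an adjusted p of 0.656. For Sox2 the difference was 0.10 (adjusted p = 0.713), for Klf4 -0.0044 (adjusted p = 0.991), for Myc 0.17 (adjusted p = 0.682) and for Nanog -0.0043 (adjusted p = 0.991). The maternally expressed RNAs of the Dlk1-Dio3 imprinted domain did not separate the classes either. Meg3, a long noncoding RNA of that domain, differed by -0.19 (SE 0.218, adjusted p = 0.828), and Rian by -0.34 (adjusted p = 0.758). Their paternally expressed neighbours Dlk1, Rtl1 and Dio3 differed by -0.28, -0.094 and -0.13, with adjusted p-values of 0.740, 0.793 and 0.825.

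The competence test with limma, with the line as a random block, called 0 of 28939 probe sets, whereas 2226 (7.69%) had an unadjusted p under 0.05. The lowest adjusted p was 0.0949, reached by Zfp943, a zinc finger gene named here after its values were seen, which was 0.37 higher in the competent lines (SE 0.0541). Of 26 gene lists, 12 were shifted with a preset correlation between genes, but 0 kept the call with an estimated correlation. The latter test had no term for the line, so more than the correlation setting changed between these tests. The list of trophectoderm genes, which mark the outer layer of the blastocyst, had a median difference of -0.21 (camera adjusted p = 1.6e-05; adjusted p = 0.147 with an estimated correlation). The fibroblast and feeder cell list had a median of -0.23 (adjusted p = 2.71e-06; adjusted p = 0.573 with an estimated correlation), and the primed epiblast list one of 0.12 (adjusted p = 2.73e-04; adjusted p = 0.491 with an estimated correlation). Single members differed in which line stood apart. Zic2, a transcription factor of the primed epiblast, was measured at 8.62 ± 0.0568 in LiPS-45, 8.64 ± 0.0618 in LiPS-57 and 8.43 ± 0.118 in LiPS-47, but at 7.41 ± 0.111 in LiPS-50 (SD, n = 3 each). Krt18 of the trophectoderm list was highest in LiPS-47, at 10.02 ± 0.0708 against 9.42 ± 0.0132 in LiPS-50, 9.55 ± 0.0962 in LiPS-45 and 9.29 ± 0.156 in LiPS-57 (SD, n = 3 each). A contrast of the 4 line means that took only the spread between cultures as error called 1789 probe sets, 936 higher and 853 lower in the competent lines. Of these, 1565 were also called in both comparisons with LiPS-50, while 162 had an unadjusted p under 0.05 in the same direction in both comparisons with LiPS-47.

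Usp26, which encodes a ubiquitin-specific protease on the X chromosome, was the single named gene that passed the test as lower in each competent line against each other line. It was measured at 4.82 ± 0.066 in LiPS-45, 5.80 ± 0.0125 in LiPS-57, 6.22 ± 0.0857 in LiPS-47 and 7.69 ± 0.091 in LiPS-50 (SD, n = 3 each), so that the 12 arrays did not overlap between classes. LiPS-45 lay below LiPS-47 by 2.63-fold (adjusted p = 1.27e-06) and below LiPS-50 by 7.28-fold (adjusted p = 4.78e-10). LiPS-57 lay below LiPS-47 by 1.33-fold (adjusted p = 0.0353) and below LiPS-50 by 3.70-fold (adjusted p = 8.07e-09). Relative to autosomal genes, 90.3% of 413 X-linked genes were higher in LiPS-50 than the mean of the other lines, with a median of 1.29-fold. The direction of the Usp26 differences from LiPS-50 is thus shared by most X-linked genes, although those of Usp26 were larger than this median. The 2 competent lines also differed from each other, LiPS-45 being 1.97-fold lower than LiPS-57 (adjusted p = 3.12e-05). Across the classes the difference was -1.64 (SE 0.337), and it did not pass the adjusted threshold once the line was a random block (unadjusted p = 2.37e-04). In all, 2 probe sets were lower and 0 higher in the competent line in each of the 4 pairs, the other being probe set 10608724, for which the annotation used here lists no gene. With the block of control probe sets included in the adjustment the count of 2 became 0, and the choice to leave that block out was made after the table and its counts had been seen. At an unadjusted p under 0.05 in each pair these counts were 59 lower and 72 higher. LiPS-45 and LiPS-47 against the other lines gave 88 lower and 104 higher. For LiPS-45 and LiPS-50 against the others they were 80 and 82, so the division by competence gave the fewest. The smallest of the Usp26 differences lost its call with quantile normalization (adjusted p = 0.0502), with median centring (0.111), with the control block included (0.0764), with LiPS-57 and LiPS-47 fitted alone (0.205) and without any 1 culture other than LiPS-50 replicates 1 and 2 (up to 0.179). The count fell from 2 to 0 or 1 when any 1 culture was left out.

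**Figure D1:**
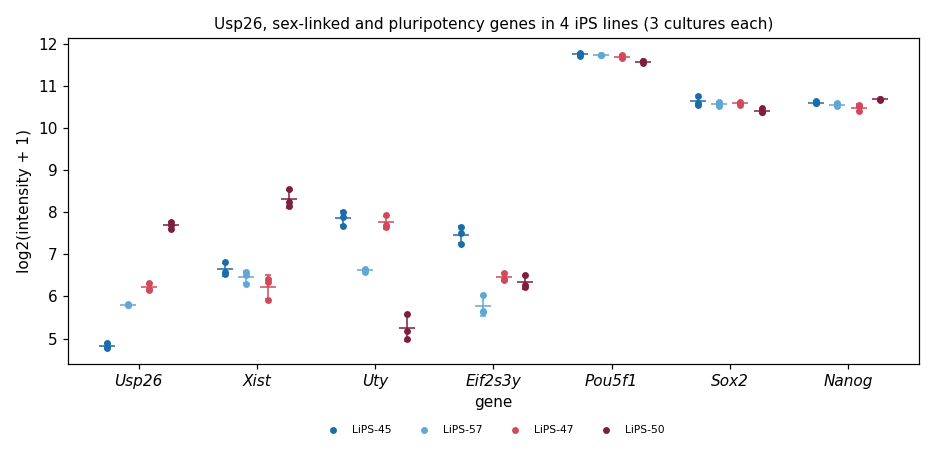
Points show log2(intensity + 1) of 7 genes in each of the 3 cultures of 4 iPS lines, with the mean as a horizontal mark and the SD as an error bar; LiPS-45 and LiPS-57 had tetraploid complementation competence. Usp26 ran from 4.82 in LiPS-45 to 7.69 in LiPS-50, Xist stood at 8.31 in LiPS-50, and Pou5f1 lay between 11.56 and 11.74 in all lines.

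The 2 competent lines differed most in the Dlk1-Dio3 domain, an imprinted region of chromosome 12 (GRCm38.p6) that holds noncoding RNAs and microRNA genes read from the maternal copy. Of 44 measured members of this list, 21 were higher in LiPS-45 than in LiPS-57 and 0 lower (34 higher and 0 lower when adjusted over the list alone). Their median difference was 0.61, and the shift kept its call with an estimated correlation (camera adjusted p = 2.18e-57; adjusted p = 9.07e-05 with an estimated correlation). Meg3 was 2.14-fold higher in LiPS-45 (log2 difference 1.10, SE 0.0786, adjusted p = 3.85e-05), at 10.70 ± 0.0798 against 9.60 ± 0.0568 (SD, n = 3 each). Rian was 2.46-fold higher (adjusted p = 3.52e-04). The microRNA genes Mir380, Mir300, Mir539 and Mir679 were 3.60-, 3.46-, 3.34- and 2.88-fold higher, with adjusted p-values between 9.98e-06 and 4.91e-04. In LiPS-57 the values of Mir380, Mir300 and Mir539 lay between 4.31 and 5.03, below the 40th percentile of probe set means at 5.21. Those of Mir679 lay between 7.05 and 7.38. The paternally expressed genes of the domain did not pass the test: Dlk1 differed by -0.060 (adjusted p = 0.952), Rtl1 by 0.25 (adjusted p = 0.483) and Dio3 by -0.19 (adjusted p = 0.806).

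Against LiPS-47, a line without competence, the same domain moved in opposite directions in the competent lines. It was lower in LiPS-57, with 11 of 44 members called lower and 0 higher (27 and 0 adjusted over the list alone), a median of -0.41 and an adjusted p of 5.98e-04 with an estimated correlation. It was higher in LiPS-45, with 1 member called higher and 0 lower (13 and 0 adjusted over the list alone), a median of 0.19 and an adjusted p of 0.0131 with an estimated correlation. Meg3 stood at 10.35 ± 0.106 in LiPS-47 and 10.32 ± 0.118 in LiPS-50 (SD, n = 3 each), between the 2 competent lines. Against LiPS-50, 20 members were lower and 1 higher in LiPS-57 (adjusted p = 0.0255 with an estimated correlation), and 16 were higher and 1 lower in LiPS-45 (adjusted p = 0.0369 with an estimated correlation). Dlk1 itself was highest in LiPS-50, at 9.56 ± 0.164 (SD, n = 3), and passed the test against each other line, for example by 1.95-fold against LiPS-47 (adjusted p = 2.07e-04). Fibroblast and feeder markers moved with Dlk1 from culture to culture within lines (r = 0.914 with the median of their list, 12 arrays). Its rise therefore cannot be assigned to the domain in the iPS cells.

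**Figure D2:**
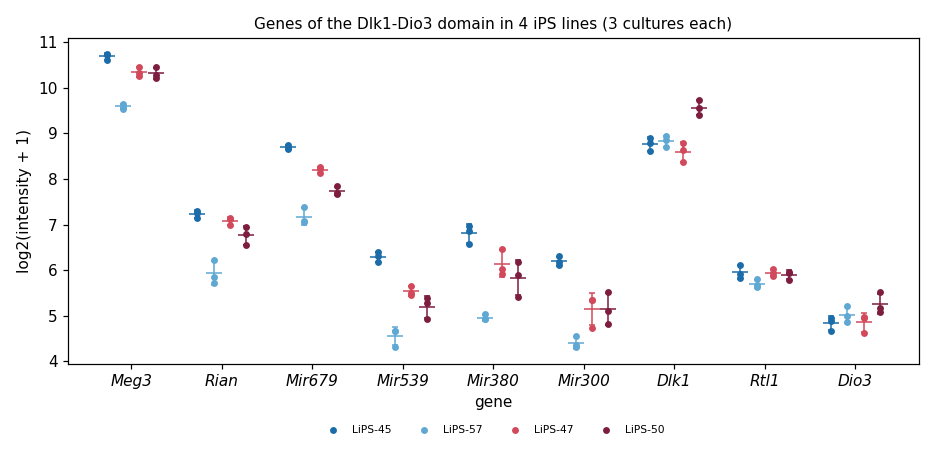
Points show log2(intensity + 1) of 9 genes of the Dlk1-Dio3 domain in each of the 3 cultures of 4 iPS lines, with the mean as a horizontal mark and the SD as an error bar. Meg3, Rian and the 4 microRNA genes were highest in LiPS-45 and lowest in LiPS-57, whereas Dlk1 was highest in LiPS-50 at 9.56.

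Outside that domain LiPS-45 and LiPS-57 differed at few genes. Eif2s3y, a Y-linked translation factor gene, was 3.22-fold higher in LiPS-45 (adjusted p = 4.37e-05), and Uty, a Y-linked histone demethylase family gene, 2.35-fold higher (adjusted p = 9.63e-04). Besides Usp26, among genes measured by a single representative probe set, those with the largest lower values in LiPS-45 were Gm11517 (log2 difference -0.59), Pianp (-0.49), Dnajc6 (-0.46) and Ciapin1 (-0.46), with adjusted p-values between 0.00955 and 0.0332. Nnat, an imprinted gene elsewhere in the genome, was 1.37-fold lower in LiPS-45 (adjusted p = 0.0269). With median centring Dnajc6 lost its call (adjusted p = 0.0562). With the control block included Gm11517, Dnajc6 and Nnat lost their calls (adjusted p = 0.0771, 0.0661 and 0.0588). With the 2 lines fitted alone Gm11517, Dnajc6, Pianp and Nnat did (0.172, 0.0962, 0.136 and 0.141). Each of these genes and Ciapin1 lost its call without some single cultures, among them LiPS-57 replicate 1 (0.138, 0.141, 0.0604, 0.0663 and 0.0504). Among the other lists, that of X inactivation and Y-linked genes had 2 members higher and 0 lower (camera adjusted p = 0.00452; adjusted p = 0.109 with an estimated correlation), and the DNA methylation list had 0 called (adjusted p = 0.0303; adjusted p = 0.889 with an estimated correlation). In total 77 probe sets were called, 62 higher and 15 lower in LiPS-45, and all 31 with at least a 2-fold difference were higher. Without single cultures of either line the count fell to between 41 and 49.

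Few genes separated either competent line from LiPS-47. LiPS-45 and LiPS-47 differed at 18 probe sets, 12 higher and 6 lower in LiPS-45, among them Eif2s3y (2.01-fold higher, adjusted p = 0.0112), Mir382 (1.68-fold higher, adjusted p = 0.0400) and Usp26. LiPS-57 and LiPS-47 differed at 46 probe sets, of which 42 were lower in LiPS-57. Besides the RNAs of the Dlk1-Dio3 domain these included the epithelial keratin genes Krt18 (1.66-fold, adjusted p = 0.00311), Krt8 (1.65-fold, adjusted p = 0.0355) and Krt19 (1.66-fold, adjusted p = 0.0365), which stand in the trophectoderm list, and Uty (2.20-fold, adjusted p = 0.00372). Tcl1, a cofactor of Akt signalling in naive pluripotent cells, was 1.34-fold higher in LiPS-57 (adjusted p = 0.0260). Mir382 lost its call with quantile normalization (adjusted p = 0.0518), with the control block (0.0781), with the 2 lines alone (0.0510) and without each culture of either line (0.0789 to 0.175). Eif2s3y lost its call with the 2 lines alone (0.0510) and without LiPS-45 replicates 2 and 3 or LiPS-47 replicate 2 (0.0835, 0.0590 and 0.0754). Krt8, Krt19 and Tcl1 lost theirs with the control block (0.103, 0.105 and 0.0558) and, like Krt18 (0.0575), with the 2 lines alone (0.336, 0.238 and 0.238). Krt8 and Krt19 kept their calls without LiPS-47 replicate 3 or LiPS-57 replicate 2, and lost them without any other culture (0.0620 to 0.152 and 0.0531 to 0.210). Tcl1 lost its call without LiPS-45 replicate 2, any LiPS-47 culture, LiPS-50 replicate 1 or LiPS-57 replicates 1 and 3 (0.0504 to 0.122). Fibroblast and feeder cell genes had medians of 0.15 for LiPS-45 and 0.13 for LiPS-57 over LiPS-47 with 0 members called (camera adjusted p = 1.62e-06 and 1.92e-07; adjusted p = 0.685 and 0.508 with an estimated correlation). Other than the Dlk1-Dio3 domain, 0 lists kept a call with an estimated correlation in these 2 comparisons. Both counts depended on single cultures: the first ranged from 6 without LiPS-45 replicate 3 to 44 without LiPS-47 replicate 3, and the second from 23 without LiPS-57 replicate 1 to 61 without LiPS-47 replicate 3. The larger part of the first count turned to lower in LiPS-45 without LiPS-47 replicate 3 (13 higher, 31 lower), without LiPS-45 replicates 1 (3 and 4) and 3 (2 and 4), and with the 2 lines alone (1 and 2).

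LiPS-50 stood apart from all 3 other lines, including the other line without competence. Depending on the line compared, 8 to 12 of 20 measured primed epiblast genes were called lower in LiPS-50 and 1 or 2 higher. Of fibroblast and feeder genes 33 of 36 were higher, of germ line genes 10 or 11 of 28, and of trophectoderm genes 8 or 9 of 20, with 0 to 3 lower. With an estimated correlation the epiblast, germ line and trophectoderm lists each passed against LiPS-45 and LiPS-57 (adjusted p = 0.0369 and 0.0255) but not against LiPS-47 (0.0532, 0.0714 and 0.0929). The fibroblast list passed against 0 of the 3 lines (0.160, 0.146 and 0.166). LiPS-47 against LiPS-50 gave 4568 called probe sets, 2115 higher and 2453 lower in LiPS-47. LiPS-45 against LiPS-50 gave 4771 (2403 higher, 2368 lower) and LiPS-57 against LiPS-50 gave 4527 (2165 higher, 2362 lower). With each array centred on its median, a larger part was lower in LiPS-50: 2590 against 2011, 3227 against 1723 and 2882 against 1753 probe sets in the same order. Among calls with at least a 2-fold difference most were higher in LiPS-50, 160 against 45, 132 against 70 and 134 against 30. In all 3 comparisons 1697 probe sets were higher in LiPS-50 and 1322 lower. Independent lists of these sizes would share 16.4 and 13.1, and 20 simulations without effects gave at most 0 in either direction. Neither is the value to be met by comparisons that share arrays and hold real effects. Few calls arise without effects, and part of the excess may come from the LiPS-50 arrays that the 3 comparisons share.

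Of 20 measured primed epiblast genes, 12 were lower and 1 higher in LiPS-50 than in LiPS-47 (13 and 1 adjusted over the list alone). The epiblast factor Zic2 was 2.03-fold lower in LiPS-50 (log2 difference LiPS-47 minus LiPS-50 of 1.02, SE 0.0774, adjusted p = 4.14e-06), Zic5 1.93-fold (adjusted p = 8.07e-06), the growth factor Fgf5 1.80-fold (adjusted p = 9.41e-05) and the DNA methyltransferase Dnmt3b 1.59-fold (adjusted p = 2.59e-05). For this list the camera adjusted p was 7.39e-07, and 0.0532 was the adjusted p with an estimated correlation, against 0.0369 and 0.0255 for LiPS-45 and LiPS-57 against LiPS-50. Some genes that mark the onset of gastrulation were lower in LiPS-50 as well: Eomes 2.47-fold (adjusted p = 7.39e-06), Fgf8 2.31-fold (adjusted p = 1.06e-05), Mixl1 1.93-fold and Wnt3 1.59-fold. Of 21 measured mesoderm and primitive streak genes 6 were lower and 2 higher in LiPS-50 (7 and 3 adjusted over the list alone; camera adjusted p = 0.0362, adjusted p = 0.217 with an estimated correlation). Foxa2, an endoderm factor, was 2.07-fold lower (adjusted p = 3.62e-05), but 8 of the 25 measured endoderm genes were higher in LiPS-50 and 1 lower, among them the receptor gene Pdgfra (2.38-fold, adjusted p = 2.91e-05; list adjusted p = 0.197 with an estimated correlation). Fibroblasts express Pdgfra too, and their markers rose in the same comparison. Among Wnt target genes 8 of 26 were lower in LiPS-50 and 3 higher, with Sp5 2.15-fold and Axin2 1.63-fold lower (list adjusted p = 0.166 with an estimated correlation).

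Fibroblast and feeder cell markers were higher in LiPS-50, with 33 of 36 called against LiPS-47 and 0 lower (34 and 0 adjusted over the list alone). The extracellular matrix genes Col3a1 and Col6a1 were 2.05-fold (adjusted p = 8.58e-05) and 1.82-fold (adjusted p = 1.64e-04) higher, the matrix metalloproteinase gene Mmp3 2.44-fold (adjusted p = 1.26e-04) and the collagen cross-linking enzyme gene Lox 1.94-fold (adjusted p = 2.32e-04). The median log2 difference LiPS-47 minus LiPS-50 was -0.82 (camera adjusted p = 3.3e-28; adjusted p = 0.166 with an estimated correlation). After the values were seen, genes outside this list were correlated with its median over 12 arrays within lines. Several went with it: Pdgfra (r = 0.928), Ccnd2 (r = 0.897), Cdkn2b (r = 0.855), B2m (r = 0.834) and Xist (r = 0.758). So did Rtl1 (r = 0.808) and Nnat (r = 0.787), and Nnat was lower in LiPS-50. Hsf2bp (r = -0.870), higher in LiPS-50, and Dnmt3a (r = -0.781), lower there, went against it. Hormad1 (r = 0.0595) and Pnma5 (r = -0.00786) were higher in LiPS-50 without such a relation. The correlation alone therefore does not tell what raised a gene in LiPS-50. Fibroblast and feeder markers were also higher in LiPS-50 than in the other lines, with medians of -0.63 for LiPS-45 and -0.62 for LiPS-57. Of 26 members of the p53 response list 16 were higher and 0 lower in LiPS-50 (16 and 1 adjusted over the list alone). The list's adjusted p was 0.0929 with an estimated correlation. The cell cycle inhibitor genes Cdkn2b (1.88-fold, adjusted p = 9.62e-05) and Cdkn2a (1.59-fold, adjusted p = 1.22e-04), which stand in this list, were among those higher. Both went with the fibroblast and feeder markers within lines (r = 0.855 and 0.605), so their rise cannot be assigned to a p53 response. The genes Eda2r and Trp53inp1 went with these markers less closely (r = 0.407 and 0.155). The correlation was taken only for genes followed through the alternatives, so it does not give the source of the rise of the whole list. Of 39 cell cycle genes 16 were lower in LiPS-50, 3 higher and 20 not called (24 lower and 3 higher adjusted over the list alone; adjusted p = 0.175 with an estimated correlation), with Cdk6 1.76-fold lower (adjusted p = 2.21e-05) and Ccnd2 1.69-fold higher (adjusted p = 5.16e-04).

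Of 28 measured germ line genes 10 were higher and 0 lower in LiPS-50 than in LiPS-47 (12 and 1 adjusted over the list alone), with the meiotic chromosome axis gene Hormad1 2.81-fold (adjusted p = 9.87e-07) and Hsf2bp 1.83-fold (adjusted p = 1.63e-05) higher; the list's adjusted p with an estimated correlation was 0.0714, and 0.0369 and 0.0255 against LiPS-45 and LiPS-57. Of 20 trophectoderm genes 8 were higher and 3 lower (8 and 3 adjusted over the list alone), with the homeobox gene Rhox9 4.69-fold, Rhox6 2.41-fold, the placental transcription factor gene Ascl2 2.40-fold and Krt7 1.77-fold higher (list adjusted p = 0.0929 with an estimated correlation). Without members on the X and Y chromosomes 5 trophectoderm genes stayed higher and 3 lower in LiPS-50, and the camera adjusted p of the list was 0.0580. Within the list of the 2-cell-like state, 2 of 14 were higher and 1 lower, with Pramel7 3.16-fold (adjusted p = 3.41e-06) and Pramel6 1.93-fold (adjusted p = 3.29e-06) higher, 2 genes linked to naive pluripotency. Members of the naive pluripotency list went both ways, 11 of 34 higher and 5 lower in LiPS-50, with Tcl1 1.98-fold and Tbx3 1.65-fold higher and Lin28a, named here as a list member only, 1.39-fold lower (camera adjusted p = 0.0902). Among the reprogramming factor genes Myc was 1.27-fold lower in LiPS-50 than in LiPS-47 (adjusted p = 0.0105), while Pou5f1 (adjusted p = 0.146), Sox2 (adjusted p = 0.115) and Klf4 (adjusted p = 0.0752) did not pass, though each did with an intensity trend and a robust prior (0.0103, 0.0238 and 0.0329). Nanog was 1.15-fold higher in LiPS-50 (adjusted p = 0.0344), a call lost with median centring (adjusted p = 0.0953), with the 2 lines alone (0.117) and without LiPS-47 replicates 1 and 3 (0.122 and 0.0561) or any LiPS-50 culture (0.0694 to 0.0893).

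Of 20 cholesterol synthesis genes 11 were lower and 2 higher in LiPS-50 (14 and 2 adjusted over the list alone), with Idi1 1.53-fold (adjusted p = 1.05e-04) and Hmgcs1 1.51-fold (adjusted p = 3.6e-04) lower and the X-linked Ebp 1.64-fold higher (adjusted p = 5.58e-05). The list's adjusted p was 0.0881 with an estimated correlation. In the glycolysis and hypoxia list 11 of 30 were lower and 7 higher, with Aldoc 1.72-fold, Pdk1 1.48-fold and Hk2 1.41-fold lower (camera adjusted p = 0.168). Without X- and Y-linked members, a choice made after seeing the data, 11 were lower and 5 higher (camera adjusted p = 0.0250). Both p-values take the preset correlation between genes and not an estimated one. Oxidative phosphorylation genes were mostly not called, 44 of 51, and 2 of those called, Ndufa1 (1.80-fold higher in LiPS-50) and Cox7b (1.55-fold), are X-linked. Histone genes were lower in LiPS-50 for 7 of 16 and higher for 1, with H1f5 1.31-fold lower (list adjusted p = 0.175 with an estimated correlation). Interferon response genes were higher for 8 of 29 and lower for 2, with B2m 1.47-fold and Tap1 1.37-fold higher (list adjusted p = 0.209 with an estimated correlation). B2m and Tap1 went with the fibroblast and feeder markers within lines (r = 0.834 and 0.685). Other imprinted genes went both ways, 13 of 44 higher and 5 lower, with Phlda2 1.68-fold and Nnat 1.67-fold lower and Zim1 1.62-fold higher (list adjusted p = 0.166 with an estimated correlation).

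Among the remaining lists, Nodal and BMP pathway genes were higher in LiPS-50 than in LiPS-47 for 9 of 23 and lower for 4 (camera adjusted p = 0.0369, or 0.0647 with X- and Y-linked genes left out; adjusted p = 0.196 with an estimated correlation). Genes of X inactivation and the Y chromosome were higher for 5 of 14 and lower for 2 (camera adjusted p = 0.109), DNA methylation genes higher for 4 of 18 and lower for 2 (adjusted p = 0.284), and Polycomb genes higher for 4 of 30 and lower for 5 (adjusted p = 0.433). For stress of unfolded proteins and amino acids 5 of 35 were higher and 9 lower (adjusted p = 0.430), for neural ectoderm 3 of 22 each way (adjusted p = 0.936), and for blood genes 1 of 12 higher and 0 lower (adjusted p = 0.170). In the Dlk1-Dio3 domain 1 of 44 was higher and 2 lower (adjusted p = 0.163), and among the 4 reprogramming factor genes 0 were higher and 1 lower (adjusted p = 0.228).

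Among genes measured by a single representative probe set, some of the largest differences between LiPS-47 and LiPS-50 were outside these lists. Pnma5, an X-linked gene, was measured at 4.76 ± 0.141 in LiPS-47 and 8.16 ± 0.0644 in LiPS-50 (SD, n = 3 each), a 10.5-fold difference (adjusted p = 1.38e-08). The predicted gene 2210409E12Rik was 5.22-fold (adjusted p = 1.43e-07) and Elobl 4.57-fold (adjusted p = 7.38e-06) higher in LiPS-50. Xist, the RNA that coats the inactive X chromosome, was 4.26-fold higher (adjusted p = 1.85e-06), at 8.31 ± 0.216 in LiPS-50 against 6.22 ± 0.276 in LiPS-47, 6.64 ± 0.154 in LiPS-45 and 6.46 ± 0.141 in LiPS-57 (SD, n = 3 each). On the other side, Fgfbp1, a carrier of fibroblast growth factors, was at 5.89 ± 0.0531 in LiPS-50 against 7.89 ± 0.124 in LiPS-47 (SD, n = 3 each; adjusted p = 4.52e-08). Lower in LiPS-50 were also Uty by 5.70-fold (adjusted p = 2.67e-07), Trh, the thyrotropin-releasing hormone gene, 3.58-fold (adjusted p = 1.38e-08), Cyp26a1, a retinoic acid-degrading enzyme, 3.39-fold (adjusted p = 1.13e-06) and the metal transporter gene Slc39a8 3.28-fold (adjusted p = 2.53e-07). The X-linked genes with Y-linked partners, Kdm5c and Eif2s3x, were 1.43-fold and 1.38-fold higher in LiPS-50, with adjusted p-values of 1.26e-04 and 1.99e-04. Eif2s3y (6.34 against 6.46) and Kdm5d (4.48 against 4.47) did not pass the test between these lines.

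**Figure D3:**
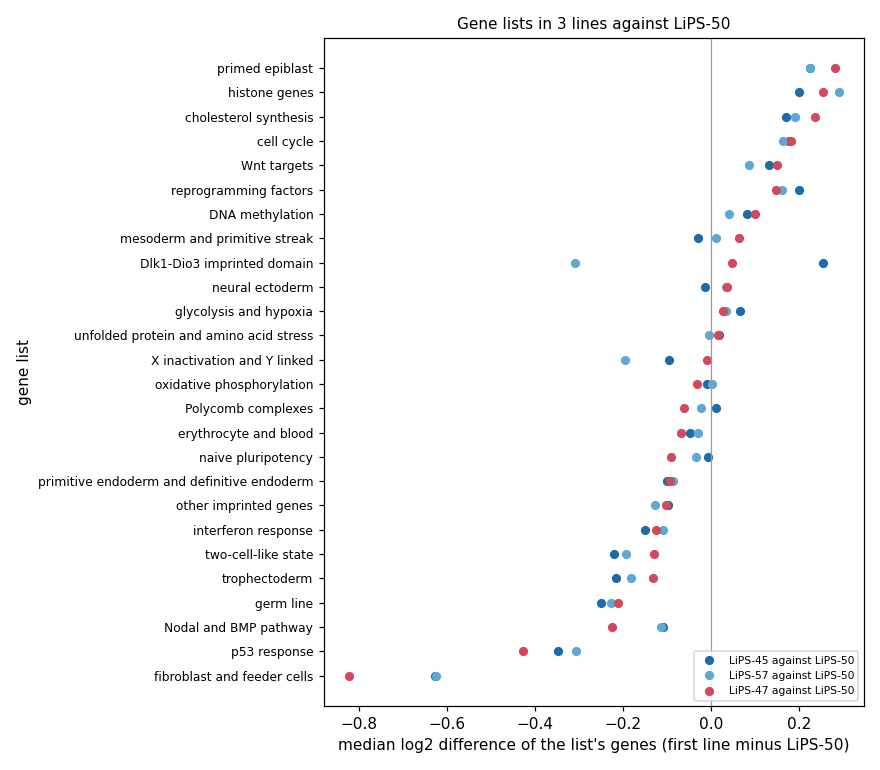
Each point is the median log2 difference of the measured genes of 1 of 26 lists, as LiPS-45, LiPS-57 or LiPS-47 minus LiPS-50, so that negative values stand for genes higher in LiPS-50. The fibroblast and feeder cell list lay lowest against all 3 lines, at -0.82 for LiPS-47, and the primed epiblast list lay above 0 for all 3.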

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

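The tests in this part were chosen after the values were seen, except the rule for a sample far from its group. Over the 6 arrays of each competence class, 194 groups of values of the genes followed through the alternatives were examined, and 1 had an array apart from the rest. Chance gives about 1 in 20 in groups of a single kind, but each group here joins 2 lines, and a difference between lines widens the range and can hide an array apart. Foxd3 was at 6.56 in LiPS-47 replicate 3, while the other 5 arrays of the lines without competence lay between 6.39 and 6.43.

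In the block of probe sets left out as controls, 2 probe sets stood far apart in a single array. Probe set 10342570 had an intensity of 13368 in LiPS-47 replicate 2 and at most 101 in the other 11 arrays, and probe set 10342663 had 8389 there and between 6.61 and 47.3 elsewhere. The next largest gap between the highest and the second highest array in this block was 2.73 on the log2 scale, against 7.04 and 7.44 for these 2 probe sets.

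The 2 competent lines departed from LiPS-47 in opposite directions in the Dlk1-Dio3 domain. The median difference of its genes was 0.19 for LiPS-45 and -0.41 for LiPS-57, and the direct comparison of these lines, which tests the difference itself, gave a median of 0.61 with an adjusted p of 9.07e-05 with an estimated correlation.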

How the results depend on the processing

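The control block and the lists without sex chromosomes were added after seeing the data. Among 164 results for single genes and 78 for gene lists, over 30 other settings where each applied, 3407 gene values kept direction and side of the threshold, 123 lost a call, 42 gained a call and 0 reversed; for lists the numbers were 1535, 73, 24 and 0. The cause was not tested unless stated. Removing dim probe sets gave 50 calls for LiPS-45 against LiPS-47 and 5 in all 4 pairs, with fewer probe sets tested. The trend with a robust prior gave 84, 80 and 135 calls for LiPS-45 against LiPS-47, LiPS-57 against LiPS-47 and LiPS-45 against LiPS-57, 4 in all 4 pairs and 1 for competence. Averaging per gene gave 10 and 29 calls for the pairs with LiPS-47. A pseudocount of 16 gave 49 for LiPS-45 against LiPS-47 and 5 in all 4 pairs. With the control block 28 were called for LiPS-57 against LiPS-47 and 0 in all 4 pairs, which was also 0 with median centring and 1 with quantile normalization. Requiring a 2-fold difference left 3, 202, 11, 164, 31 and 205 calls in the order LiPS-45 against LiPS-47 and LiPS-50, LiPS-57 against LiPS-47 and LiPS-50, LiPS-45 against LiPS-57 and LiPS-47 against LiPS-50, and 0 in all 4 pairs. Fits of 2 lines alone, with fewer arrays, gave 3, 19 and 49 for LiPS-45 against LiPS-47, LiPS-57 against LiPS-47 and LiPS-45 against LiPS-57. For competence, 4 probe sets were called with no term for the line, 1789 with fixed line means, 6711 without LiPS-47, 1 without LiPS-50 and 0 with line means (766 at an unadjusted p under 0.05). Without LiPS-47 the class without competence is LiPS-50 alone, so the 6711 calls cannot tell competence from that line.

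The replicate numbers did not pair the cultures: over 18 pairs of arrays of different lines with the same number, the correlation of deviations from line means lay between -0.17 and 0.12, with a median of 0.0117 against 0.00520 for other numbers, and 5 of 12 arrays correlated best with an array of their own number. With the number as a block Usp26, Krt8 and Tcl1 in LiPS-57 against LiPS-47 (adjusted p = 0.0717, 0.0712 and 0.0648), Nnat in LiPS-45 against LiPS-57 (0.0856) and Nanog in LiPS-47 against LiPS-50 (0.0520) did not pass, and the calls were 25 for LiPS-57 against LiPS-47 and 1 in all 4 pairs; the other counts moved by less than 1.5 times, for example to 4257 for LiPS-47 against LiPS-50.

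Leaving out 1 culture gave 6 to 44 calls for LiPS-45 against LiPS-47, 3106 to 4802 for LiPS-45 against LiPS-50, 23 to 61 for LiPS-57 against LiPS-47, 3193 to 4555 for LiPS-57 against LiPS-50, 41 to 70 for LiPS-45 against LiPS-57, 3523 to 4418 for LiPS-47 against LiPS-50, 0 to 1 in all 4 pairs and 0 to 0 for competence. By more than 1.5 times, LiPS-45 against LiPS-47 moved without LiPS-45 replicates 1, 2 and 3 (7, 8, 6), LiPS-47 replicates 1, 2 and 3 (11, 8, 44) and LiPS-57 replicate 3 (11). LiPS-57 against LiPS-47 moved without LiPS-45 replicate 2 (29), LiPS-47 replicates 1 and 2 (24, 27) and LiPS-57 replicates 1 and 3 (23 each). LiPS-45 against LiPS-57 moved without LiPS-45 replicates 1, 2 and 3 (49, 48, 44) and LiPS-57 replicates 1, 2 and 3 (41, 46, 46), and LiPS-45 against LiPS-50 without LiPS-45 replicate 3 (3106). The precision of dim genes is limited by the distance of their signal from the background, which the deposited values do not give.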

Other observations

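Some gene families can be read on this array through probe sets shared by several copies, which name no single gene. All 3 probe sets of the Zscan4 family, known from the 2-cell embryo and from a small part of embryonic stem cells, were higher in LiPS-50 than in each of the other lines, by 3.16 to 3.52 on the log2 scale over the mean of those lines. All 8 probe sets of the X-linked Xlr3, Xlr4 and Xlr5 family were higher as well, by 1.68 to 3.81, and so were 18 of 33 of the Pramel family, with 0 lower and a median of 0.46. The 5 probe sets of the oocyte homeobox family Obox had a median difference of 0.019, and the 3 of the Magea family one of 0.079; 0 of either family passed in all 3 comparisons. All 5 families were chosen after their values were seen.

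The X-linked phosphatase gene Dusp9, an antagonist of MAP kinase signalling, was at 10.22 in LiPS-50 against 8.98, 8.99 and 9.15 in LiPS-45, LiPS-57 and LiPS-47, with adjusted p-values of 2.89e-07, 3.07e-07 and 1.11e-06. The de novo DNA methyltransferase genes Dnmt3a and Dnmt3b were lower in LiPS-50: Dnmt3a by 0.35, 0.43 and 0.42 against the same lines (adjusted p = 0.00122, 3.32e-04 and 3.53e-04) and Dnmt3b by 0.70, 0.61 and 0.67. Their cofactor gene Dnmt3l was higher in LiPS-50 than in LiPS-57 by 0.30 and than in LiPS-47 by 0.22 (adjusted p = 0.00231 and 0.0112) and did not pass against LiPS-45 (adjusted p = 0.454). The maintenance gene Dnmt1 did not pass in any of these comparisons (adjusted p = 0.474, 0.343 and 0.203). These genes were chosen after their values were seen. Within lines Dnmt3a fell as the median of the fibroblast and feeder list rose (r = -0.781), and Dnmt3b did so less closely (r = -0.478). Whether fibroblast-like cells contributed to the lower values in LiPS-50 was not tested. For Baiap2l1, probe set 10535559 was at 10.09 in LiPS-50 and between 6.01 and 6.18 in the other lines (adjusted p = 6.2e-09 against LiPS-47), while the 2 brighter probe sets listed for this gene did not differ, at 13.70 and 11.51 in LiPS-50 against 13.66 and 11.47 in LiPS-47.

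In this and the following paragraphs all tests were chosen after the result was seen, except the tests by blocks of genes and the divisions of 6 arrays. X-linked genes were higher in LiPS-50: over 413 X-linked genes above the dim level, the median difference from the mean of the other lines was 0.37 relative to autosomal genes, and 90.3% of them were higher. A shift shared by genes of the same brightness is argued against, since 1000 autosomal lists matched on mean level reached at most 0.0303. A few genes or a single region are argued against as well, because the lowest of 10 blocks of genes in chromosome order had a median of 0.27. A hypothesis is that LiPS-50 cells carry a larger dose of the X chromosome, such as a second active copy in many cells; the lowest LiPS-50 array exceeded the highest of the 9 other arrays by 0.32, which restates the rise and does not test the hypothesis. The rise of 1.29-fold is short of a doubling, higher Xist would also mark cells with an inactive copy and went with the fibroblast markers within lines (r = 0.758), and neither copy number nor the state of the X chromosomes was measured. Among Y-linked genes, Uty was lower in LiPS-50 than in LiPS-47, whereas Eif2s3y and Kdm5d did not pass between these lines. Whether the lines differ in sex or in Y-linked material was not tested.

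Fibroblast and feeder genes were higher in LiPS-50, with a median difference of 0.71 from the mean of the other lines, while 1000 lists matched on mean level reached at most 0.0793, which argues against a shift shared by genes of the same brightness. Of the 36 genes, 35 lay above the dim level, and all 35, or 100%, were higher in LiPS-50 than in each other line, by 0.16 to 1.06. The most abundant of them, Vim, Fn1, Thbs1 and Acta2, were higher by 0.34, 0.43, 0.55 and 0.42. These differences restate the rise over a list where it had been seen, and do not test its source. The markers were bright in the other lines as well, with Vim at 12.32, 12.27 and 12.30 in LiPS-45, LiPS-47 and LiPS-57. The median of the list lay between 8.14 and 8.75 on the arrays of these lines, and between 9.18 and 9.38 on those of LiPS-50. The labels do not say whether the cultures were grown on feeder cells. More feeder cells or leftover fibroblasts in the LiPS-50 cultures could raise these genes, and fibroblast-like cells made by the line itself would raise the same 35, so the sources cannot be told apart here, and how many of these genes pluripotent cells express was not tested.

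Chromosome 8 genes were higher in LiPS-57 by a small amount: over 705 genes the median difference from the mean of the other lines was 0.052 relative to autosomal genes, a factor of 1.04, and 68.2% were higher. Matched lists from other autosomes reached at most 0.0131, and the lowest of 10 blocks in chromosome order had a median of 0.031, which argue against a shift of genes of the same brightness and against a few genes or a single region. Whole chromosomes vary more than such lists: chromosome 13 was at -0.036 and chromosome 3 at -0.027 in LiPS-50, and both at 0.022 in LiPS-45, with no cause known here. The lowest LiPS-57 array exceeded the highest of the 9 other arrays by 0.041, which restates the rise and does not test its source. A hypothesis is an extra copy of chromosome 8 in part of the LiPS-57 cells, since a copy in all cells would be 0.58 if expression followed the dose; 20 chromosomes in each of 4 lines had been looked through before this one was singled out, and the copy number itself was not measured.

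The 4 lines can be divided into pairs in 3 ways. The division by competence gave 0 calls, and the highest of the other divisions gave 14. For probe sets called in the same direction in all 4 pairs the division by competence gave 2 and the highest other 17. With 3 divisions no share under 0.05 can be reached. For the pairs of lines, each set of 6 arrays can be divided 3 against 3 in 10 ways, too few for a share under 0.05. The real division gave 18, 4771, 46, 4527, 77 and 4568 calls for LiPS-45 against LiPS-47 and LiPS-50, LiPS-57 against LiPS-47 and LiPS-50, LiPS-45 against LiPS-57 and LiPS-47 against LiPS-50. The highest of the other 9 gave 0, 0, 0, 1, 1 and 0 calls, so in each case 1 of the 10 divisions, the real one, reached the count. Each of the other divisions mixes arrays of both lines, so real differences between the lines enter its spread within groups. Few calls there follow from such differences, so these counts do not give the number that chance alone would reach.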
